A study of Drosophila melanogaster with 2 samples.

How the data were processed

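Chromatin of whole Drosophila melanogaster pupae carrying a D1-eGFP transgene was sonicated, with a size range of 200 to 800 per the labels, and precipitated with an anti-GFP antibody in 2 biological replicates. Both were placed in 1 group from the labels, which also give the replicate numbers. Each peak list gives a signal and a -log10 q value per peak, made by the authors, and a summit position. Per the deposited text notes, peaks were called on the alignments of each replicate, and of both together, with a control file, and the IDR set was derived from the 2 replicate lists and the pooled list. The aligner, the peak caller, the IDR threshold and the scale of the signal are not given in the sources used here. The assembly is dm6 per the labels. The deposited -log10 q values are tied at the maximum of each list (2286 IDR peaks at 3.66), so peaks were ranked by the deposited signal. The 3 lists of 30000 peaks have the same length, so their length says nothing of the number of bound sites. Read depth is unknown, and no interval that needs it is given.

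The IDR set was exactly the 3388 highest peaks of the pooled list. Taking that many of the highest pooled peaks therefore gives the same set. The spread between replicates is the SD of a quantity over the 2 replicates' own lists, each with its 3388 highest peaks. Positions are 1-based. The reference was the NCBI sequence of the Release 6 assembly with Ensembl release 115 annotation, and every peak ended within its chromosome's length. Transposable elements were not counted as genes.

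Chromosome density used summits and lengths without N bases. The centromere-proximal segments were fixed as 2L from 22 Mb, 2R to 6 Mb, 3L from 23 Mb, 3R to 4 Mb and X from 22 Mb. Each summit was given 1 of 7 feature classes in the order promoter (within 500 bp of a start), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Composition and words were taken in 200 bp windows, words on either strand, against 1000 sets of random positions matched on chromosome and feature class. Empirical p values are two-sided, and the smallest possible is 0.001998. A gene was bound where an IDR summit lay within 500 bp of any of its starts. The 24 gene lists were tested with Fisher's exact test against protein-coding genes, or against all genes for tRNA genes. Promoter and other signal were compared with 100000 permutations. Adjusted p values are Benjamini-Hochberg within each family, with a threshold of 0.05. Bound neighbours and genes sharing a promoter are not independent, and nearby peaks are not independent either, so these p values are too small to an unknown degree. Of the list symbols, GAGA, roX1 and roX2 matched no gene under that spelling. Members that are not protein-coding, such as both non-coding RNA genes of the dosage compensation list, were left out of the tests.

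Named genes followed a rule fixed before the data were examined: the nearest start's gene at the 15 highest promoter peaks, up to 3 bound members with the highest signal of each list past the threshold and of the ecdysone, Hox, heterochromatin, insulator and dosage compensation lists, the D1 gene, the 5 highest peaks away from starts, and the 2 highest on chromosome 4. The rule allows at most 30 genes, and its parts together gave more, so all were named. The genes that contain those peaks and the genes named among the other observations were chosen after their values were seen.

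Alternatives were the 1694 highest IDR peaks, each replicate's list alone, IDR peaks covered over at least 50% of their length in both replicate lists, other overlap criteria, windows of 100 and 500 bp, starts within 250 and 1000 bp, peak midpoints, gene bodies, genes with no other start within 1 kb, full chromosome lengths, the 2 Mb of each arm nearest the centromere, and random positions matched also on AT content within 2.5 points or less closely. Of the IDR peaks 94.1% had a width of 420 bp, and named peaks of that width had the summit at the middle. Midpoints could therefore change little. A density comparison over the 6 chromosomes that hold peaks and a comparison of gene lists within strata of start number and quintile of gene length, by Mantel-Haenszel odds ratio and 10000 matched random lists, were chosen after seeing the data. Matched lists were drawn from genes outside the tested list, and their drawing was recoded after its first values had been seen.

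The calculations were tested on simulated data, although the tests on simulated data were written after the main values had first been computed. With no effect, unadjusted p under the threshold came in 4 of 140 feature tests, 11 of 280 word tests, 2 of 20 AT tests, 14 of 480 Fisher tests and 7 of 480 stratified tests. Moving 400 peaks to promoters raised their share by 12.1 points where 11.8 were planted. Lists with 9 of 24 genes bound were called in 100 of 100 sets by each test. Their genes were drawn from all coding genes, whatever their start number and length. These sets therefore do not show how often the stratified test would call such a list of long genes with many starts. Of 100 random lists of 24 long genes with 3 or more starts, Fisher's test called 96 and the stratified test 3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.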

Results

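D1 is a chromosomal protein of Drosophila melanogaster with AT hooks, short segments that bind A/T-rich DNA, and it is known from AT-rich satellite repeats. Its binding to the genome was measured by ChIP-seq, with an antibody against GFP, in whole pupae that carry D1 fused to eGFP. The labels give a pupal age of 24 hours and 2 biological replicates of 1 group. There was no second condition, so no test compared conditions, and the questions were where D1-eGFP peaks lay and what sequence and which genes lay there. The data were 4 peak lists on the dm6 assembly: 30000 peaks for each replicate, 30000 for both replicates pooled, and the authors' set of 3388 peaks selected by the irreproducible discovery rate (IDR). The number of reads is unknown, since the files hold peaks only. The signal of a peak is the authors' own value. Its scale is not given in the sources used here, so peaks are ranked only within a list, and whether signals of different lists are on the same scale is open.

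The replicates shared most of their highest peaks. When the 3388 highest peaks of each replicate were compared, 70.7% of those of replicate 1 overlapped one of replicate 2 by at least 1 bp, against 2.06% over 1000 random placements on the same chromosomes. The empirical two-sided p was 0.001998, the smallest that 1000 placements can give. Of the 3388 IDR peaks, 3351 (98.9%) overlapped a peak of each replicate's list, against 10.3% by random placement, but the IDR set was derived from those lists, so this share is set largely by the selection and is no independent measure of how far the replicates share peaks. Across the 3114 IDR peaks with a summit of each replicate within 100 bp, the log2 signals of the replicates had a Pearson r of 0.645 and a Spearman rho of 0.591. These are correlations across peaks, and peaks are not independent replicates. The IDR peaks were also the highest of the pooled list, which narrows the range of signal that the correlations cover. The SD of the log2 difference between replicates was 0.53.

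The highest peaks lay next to genes of varied function. The highest of all, with a signal of 1204, was on 3R at 28326419 to 28326768, 328 bp upstream of the nearest start of larp, which encodes an RNA-binding protein. The next promoter peaks were at CG14100 (signal 1124, 3L at 19590461 to 19590750) and scb (signal 1110, 2R at 15248402 to 15248750), which encodes an integrin subunit. Ugalt, a UDP-galactose transporter gene, had a signal of 919, CG18428 had 898, and C1GalTA, which encodes a galactosyltransferase, had 897. PNPase (890), which encodes a polynucleotide phosphorylase, and CG18549 (890) followed. The D1 gene itself had the peak of rank 14. The glycolytic gene Gapdh2 had a signal of 835, the small heat shock protein gene Hsp27 831, cu 801, Tina-1 765, the mitochondrial ribosomal protein gene mRpL41 737 and CG11309 735. At larp the signals were 548 in replicate 1 and 655 in replicate 2. The CG14100 peak was the highest of replicate 1 (567), and the list of replicate 2 had no entry there, with its nearest summit 5373 bp away. The pooled signal less that of replicate 1 left 557 at this peak, so its missing entry does not show that replicate 2 lacked signal there.

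The 5 highest peaks more than 500 bp from any start lay in introns and non-coding exons, 504 to 1360 bp from the nearest start. A peak with signal 1152, rank 2 of the set, had its summit on X at 12751319 in an exon of lncRNA:Vinr, 548 bp from the start of lncRNA:CR44619, and an exon of lncRNA:CR44619 held another with signal 861. An intron of ush, which encodes a Friend-of-GATA cofactor, held a peak with signal 953 on 2L, with its summit at 481048 and the start of cbt nearest. An intron of CG11050 held a peak with signal 952. Sequence annotated as intron in both HmgD and HmgZ, which encode HMG-box chromosomal proteins, held a peak with signal 881 on 2R, with its summit at 21703432. On chromosome 4 the highest peak, with signal 409, lay in an intron of Mitf, a transcription factor gene, 589 bp from the nearest start. The next, with signal 337, lay 479 bp upstream of a start of pan, which encodes the TCF factor of Wnt signalling. Mean signal was 245 at promoter peaks and 232 at other peaks, a ratio of 1.06 (permutation test, two-sided, p = 0.00088). The medians were nearly equal, 202 and 201. Over 4 equal groups of peaks from the highest signal to the lowest, promoters held 41.1%, 34.8%, 37.3% and 36.8%.

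Peaks were densest on chromosome 4, which is small and largely heterochromatic, and on 3L. AT content was 64.7% on chromosome 4, against 57.4% to 58.4% on the other chromosomes that hold peaks. Whether AT content accounts for the density on chromosome 4 was not tested. Chromosome 4 held 66 IDR peaks, or 49.6 per Mb with an exact 95% Poisson interval of 38.3 to 63.1, which was 2.01 times its share of the genome's length. On 3L, 913 peaks gave 32.6 per Mb (30.5 to 34.8), a ratio of 1.32. The replicates' own lists gave 50.7 per Mb ± 3.72 (SD, n = 2) on chromosome 4 and 33.0 ± 0.0505 (SD, n = 2) on 3L. Density was 27.8 per Mb on 2L, 22.6 on 3R, 21.7 on X and 20.6 on 2R. Outside the centromere-proximal segments it was 26.1 per Mb on 2R, 25.8 on 3R and 23.1 on X. The density of 2R was thus the lowest of these only with its 6 Mb segment counted. On Y, 0 peaks lay in 3.41 Mb, and none of the 4 lists held a peak there. Whether the authors kept reads on Y is not given in the sources used here. In exact binomial tests against length, two-sided and Benjamini-Hochberg adjusted over 7 chromosomes, the adjusted p was 6.12e-07 for chromosome 4, 3.11e-19 for 3L, 4.1e-06 for 2R, 0.0014 for both 2L and X, 0.00614 for 3R and 1.18e-36 for Y. Among the 1694 highest IDR peaks the ratios on chromosome 4 (1.40), 2L (1.08) and 3R (0.934) no longer passed, and on the list of replicate 1 alone those of 2L (1.06) and 3R (0.967) did not pass. The intervals cover counting error only.

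**Figure D1:**
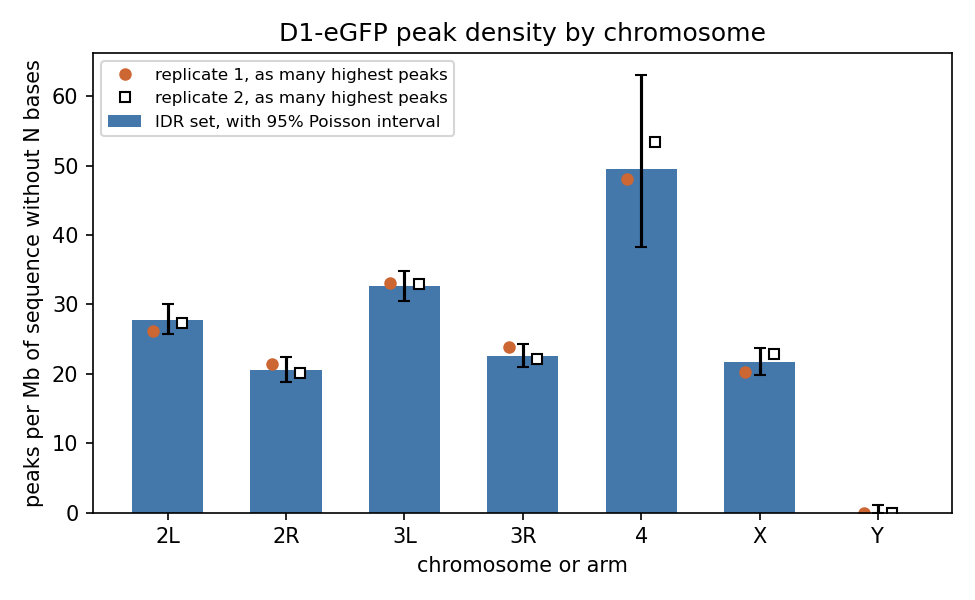
IDR peaks per Mb on each chromosome, with exact 95% Poisson intervals, and the values of the 2 replicates' own lists of 3388 highest peaks. Chromosome 4 has the highest density, 49.6 per Mb, and Y has none.

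Few peaks lay in the centromere-proximal segments of the arms, where pericentromeric heterochromatin is assembled. Of 3322 IDR peaks on 2L, 2R, 3L, 3R and X, 24 lay there, which is 0.722% (exact Clopper-Pearson 95% interval 0.463 to 1.07) against 13.6% of the length. The ratio was 0.0532 (exact binomial test, two-sided, p = 1.76e-169). The segment of 2R held 16 of the 24 peaks, or 2.67 per Mb against 26.1 on the rest of that arm. The segment of 3L held 0.8 per Mb against 39.5 outside it. The replicates' own lists gave 0.693% ± 0.299 (SD, n = 2). The ratio was 0.022 among the 1694 highest IDR peaks, 0.0355 on the list of replicate 1 alone and 0.0666 on that of replicate 2 alone. Among the 26612 pooled peaks below the IDR set the deficit was smaller, with 2.74% in the segments and a ratio of 0.202.

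Promoters held more peaks than their length accounts for, and coding sequence held very few. Within 500 bp of an annotated start lay 1271 summits, 37.5% of the set, against 13.5% of random positions on the same chromosomes. Only 7 summits (0.207%) lay in coding exons outside promoters, against 13.1% of random positions, and 46 (1.36%) lay in 3' UTRs, against 5.01%. Coding exon sequence had 48.1% AT over the genome, the lowest of the 7 classes. The coding exon share was not compared at equal AT content, so base composition may account for part of this deficit. Introns held 1322 summits (39.0% against 39.2%) and intergenic sequence held 684 (20.2% against 27.5%). The random positions included repeated sequence, where reads may not be placeable. No feature share was compared within unique sequence alone, so how far this moves the promoter and intergenic shares is open. The empirical two-sided p, Benjamini-Hochberg adjusted over 7 classes, was 0.0035 for promoters, coding exons, 3' UTRs and intergenic sequence, the smallest that 1000 sets can give here. The shares in introns (0.797), 5' UTRs (0.590%, 0.345) and other exons (1.12%, 0.137) did not pass, each with its adjusted p last in parentheses. The replicates' own lists gave a promoter share of 38% ± 1.25 (SD, n = 2) and a coding exon share of 0.118% in each replicate. Of the promoter summits, 998 (78.5%) lay upstream of the nearest start and 271 downstream, with a median of -162 bp and quartiles of -273.5 and -39.5 bp. With promoters set at 250 bp the share was 24.0%, against 7.46% of random positions.

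**Figure D2:**
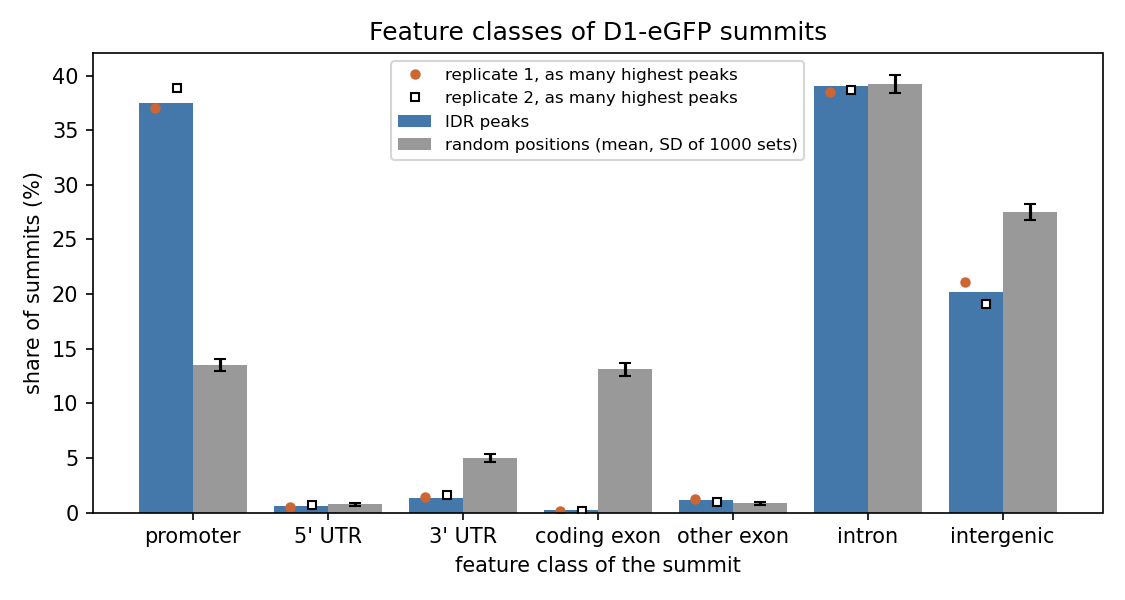
Percent of IDR summits in each annotated feature class beside the mean of 1000 sets of random positions on the same chromosomes, with the 2 replicates' own lists as points. Promoters hold 37.5% of summits against 13.5% of random positions, and coding exons 0.207% against 13.1%.

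Sequence at the peaks was rich in A and T. The 200 bp around the summits had a mean AT content of 66.6% (SD 6.89 over 3388 peaks), against 58.9% at random positions matched on chromosome and feature class, a difference of 7.69 percentage points. The replicates' own lists gave 66.3% ± 1.18 (SD, n = 2). The longest uninterrupted run of A or T averaged 14.3 bp against 10.8 bp at matched positions. The empirical two-sided p was 0.001998 for each measure, the smallest possible. Promoter peaks had 66.5% AT against 57.3% over all promoter sequence, intron peaks 66.5% against 59.8%, and intergenic peaks 67.1% against 59.2%. Over 4 equal groups of 847 peaks, from the highest signal to the lowest, mean AT content was 68.2%, 67.0%, 65.8% and 65.2%. AT content was 68.5% in the 21 bp at the summit and fell to 57.1% at 310 bp upstream of it in chromosome coordinates and to 56.7% at 290 bp on the other side. Matched random positions had 58.6% and 58.3% at those offsets. In windows of 500 bp the difference from matched positions was 3.43 points.

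**Figure D3:**
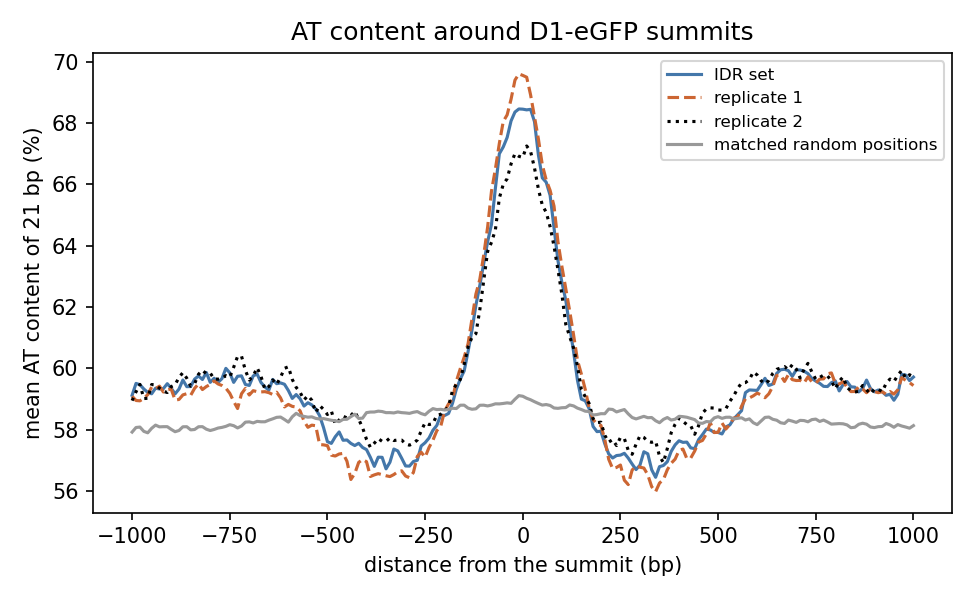
Mean AT content in percent, over 21 bp, by distance in bp from the summit, for the IDR set, each replicate's 3388 highest peaks and matched random positions. The profile of the IDR set reaches 68.5% at the summit, against 59.1% at random positions.

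Among 14 DNA words fixed before the data were examined, A/T-rich words were more frequent at peaks, and several factor motifs were less frequent. AATAT, the unit of a satellite that D1 is known to bind, lay in 75% of windows against 51.1% of matched random windows, a ratio of 1.47. A pair of tandem units, AATATAATAT, lay in 1.45% against 0.507% (2.85). The run AAAAAAAA had a ratio of 1.66, ATATATAT 1.38, the TATA box word TATAAA 1.67, the DREF word TATCGATA 1.86 and the M1BP word GGTCACACT 1.91. The Zelda word CAGGTAG (0.649), the E-box CACGTG (0.625) and the nuclear receptor word AGGTCA (0.688) were less frequent. The adjusted p over 14 words was 0.0035 for these, except GGTCACACT (0.00622) and CAGGTAG (0.042). The other words did not pass: GAGAG, bound by GAF (0.976), CGATA of BEAF-32 (1.01), AATAACATAG of the Prod satellite (1.45) and AAGAGAAGAG of the AAGAG satellite (1.03). Random windows were then also matched on AT content, within 2.5 points. Their mean was 66.3% against 66.6% at the peaks, so a small excess of AT remained at the peaks. With this match AATAT had a ratio of 1.06, AAAAAAAA of 1.13, GGTCACACT of 1.74 (adjusted p of 0.0466) and AGGTCA of 0.795 (0.0392), all past the threshold. AATATAATAT (1.32, with an adjusted p of 0.112), TATCGATA (1.33, 0.0759), TATAAA (1.04, 0.131), CAGGTAG (0.968, 0.906) and CACGTG (0.951, 0.897) then no longer passed, ATATATAT turned to 0.813 (0.035), and GAGAG passed at 1.32 (0.00932). Among the 1694 highest peaks TATCGATA (1.53), CAGGTAG (0.797) and GGTCACACT (1.90) did not pass. TATCGATA also did not pass on the list of replicate 1 alone (1.38), GGTCACACT in 100 bp windows (1.22), and CAGGTAG in 500 bp windows (0.818) or among peaks covered over 50% of their length in both replicate lists (0.662).

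**Figure D4:**
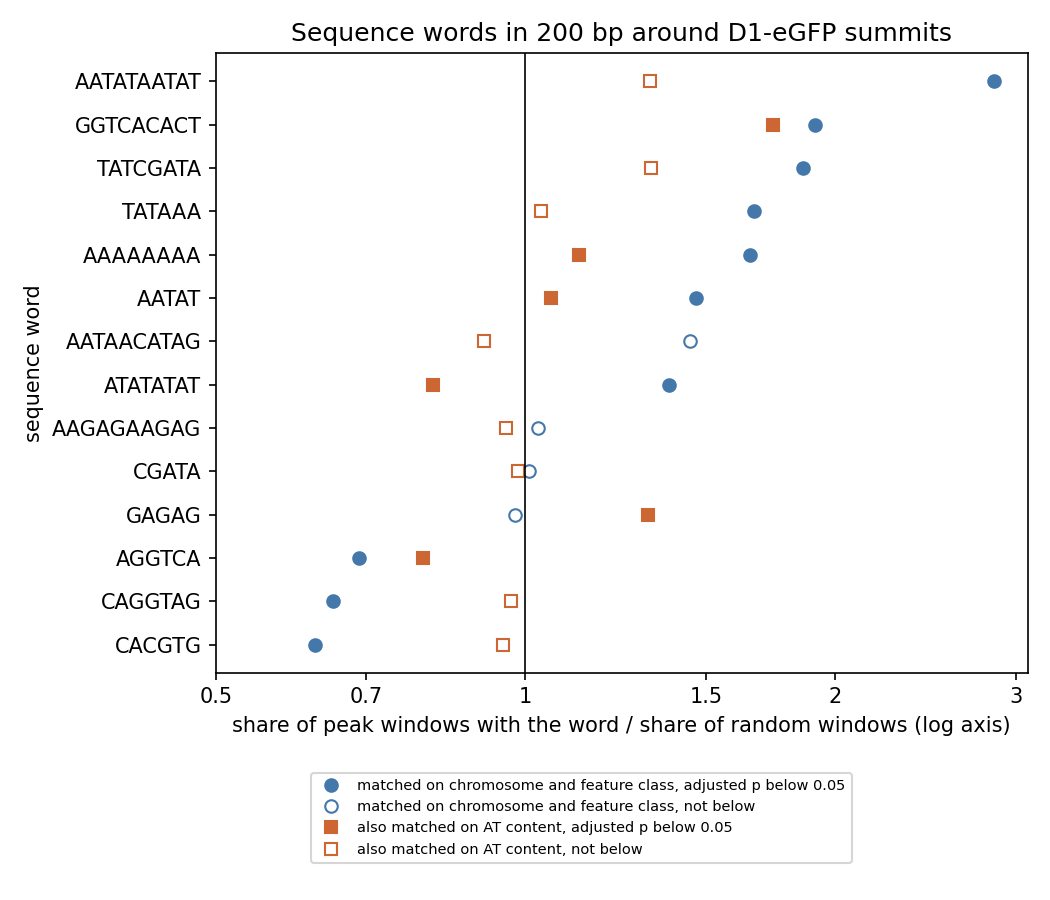
Ratio of the share of 200 bp windows at IDR summits that hold each word to the share of random windows, on a log axis, with circles for windows matched on chromosome and feature class and squares for windows matched also on AT content. Filled marks have an adjusted p under 0.05, and AATATAATAT lies highest among the circles, at 2.85.

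Ecdysone response genes, which act in metamorphosis, were the gene list with the highest share of bound promoters. A summit lay within 500 bp of a start in 9 of 24 genes (37.5%), against 1180 of all 13968 protein-coding genes (8.45%), an odds ratio of 6.54 (95% interval 2.52 to 16; adjusted p = 0.000781, Fisher's exact test, two-sided, over 24 lists). The highest of these peaks were at E23 (signal 529), an ecdysone-induced ABC transporter gene, and at the nuclear receptor genes Hr78 (268) and Eip75B (266). Among imaginal disc patterning genes 8 of 37 were bound (odds ratio 3.0, 1.18 to 6.75; adjusted p = 0.0428, Fisher's exact test), with the highest peaks at Delta (332), a Notch ligand gene, the Pax6 gene toy (309) and ci (242), the transcription factor gene of Hedgehog signalling. Ecdysone response genes had a median of 3 starts and a length of 24035.5 bp, against 1 start and 2164.5 bp over all coding genes. Neither call held when genes were compared within strata of start number and gene length (stratified permutation test of list membership): the odds ratios were 2.20 (adjusted p = 0.469) and 1.53 (adjusted p = 0.899). By Fisher's exact test the patterning call was also lost on the list of replicate 1 alone (1.65, adjusted p = 0.596), among the 1694 highest peaks (2.55, adjusted p = 0.343), with starts within 1000 bp (2.71, adjusted p = 0.0536) and among genes with no other start within 1 kb (2.79, adjusted p = 0.201).

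Chemoreceptor genes carried no IDR promoter peak. None of 179 was bound (odds ratio 0, upper bound 0.223, adjusted p = 5.01e-06, Fisher's exact test), and the matched-list test within strata of start number and gene length also passed (adjusted p = 0.0024). Cuticle protein genes were rarely bound, with 2 of 121 (odds ratio 0.181, adjusted p = 0.0168, Fisher's exact test), namely Cpr72Ea (signal 198) and Cpr72Eb (150). That call was lost in the matched-list test within the strata (0.360, adjusted p = 0.595), and by Fisher's exact test among the 1694 highest peaks (0, adjusted p = 0.0551) and among genes with no other start within 1 kb (0.226, adjusted p = 0.129). None of 111 replication-dependent histone genes was bound (odds ratio 0, upper bound 0.364; adjusted p = 0.000781, Fisher's exact test). These genes are repeated copies: 0.849% of the sequence near their starts consists of 31-base words that occur once in the genome, against 96.7% over all starts. The histone call was lost in the matched-list test within the strata (adjusted p = 0.25), and by Fisher's exact test among the 1694 highest peaks (0.0608) and among genes with no other start within 1 kb (0.677).

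Of 290 tRNA genes 35 were bound, through 26 distinct peaks, against 1384 of all 18277 genes (odds ratio 1.69, 1.15 to 2.43; adjusted p = 0.0325, Fisher's exact test). The highest were at tRNA:Arg-TCG-2-4 (signal 343), tRNA:Tyr-GTA-1-8 (341) and tRNA:Pro-CGG-2-3 (332). Within the strata the odds ratio was 3.68 (adjusted p = 0.0024, permutation test). It fell below 1, by Fisher's exact test, among the 1694 highest peaks (0.765, adjusted p = 0.82) and among genes with no other start within 1 kb (0.767, adjusted p = 0.981). It did not pass Fisher's exact test on the list of replicate 1 alone (1.29, adjusted p = 0.585) or when gene bodies were counted (1.14, adjusted p = 0.766). Mitochondrial ribosomal protein genes had 9 of 73 bound and did not pass (odds ratio 1.53, adjusted p = 0.5, Fisher's exact test), but did in the matched-list test within the strata (3.68, adjusted p = 0.0256). Among genes with no other start within 1 kb, 0 of 13 were bound.

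The other 17 lists did not pass Fisher's exact test. Polycomb and trithorax genes had 5 of 29 bound (adjusted p of 0.279), neuronal genes 5 of 24 (0.161) and cell death genes 3 of 15 (0.34). Of the heterochromatin and satellite DNA protein genes 2 of 29 were bound, D1 and HP4 (signal 244), and of the insulator and promoter protein genes 2 of 22, row (213) and Trl (169), the GAGA factor gene. The Hox list had 1 of 8 bound, Dfd (161). Dosage compensation genes had 0 of 7 bound. Cytosolic ribosomal protein genes had 5 of 92, nucleosome remodelling and chromatin assembly genes 2 of 17, proteasome genes 1 of 32, heat shock genes 1 of 21, and eggshell genes 1 of 17. Among markers of cell types, muscle had 1 of 26 bound, fat body and haemolymph 1 of 14, haemocyte 0 of 13 and germline 0 of 18, and antimicrobial peptide genes had 0 of 14. Their adjusted p ranged from 0.161 to 1. A small list gives a wide interval, as for dosage compensation, whose odds ratio had an upper bound of 7.52, so these results do not exclude a difference.

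**Figure D5:**
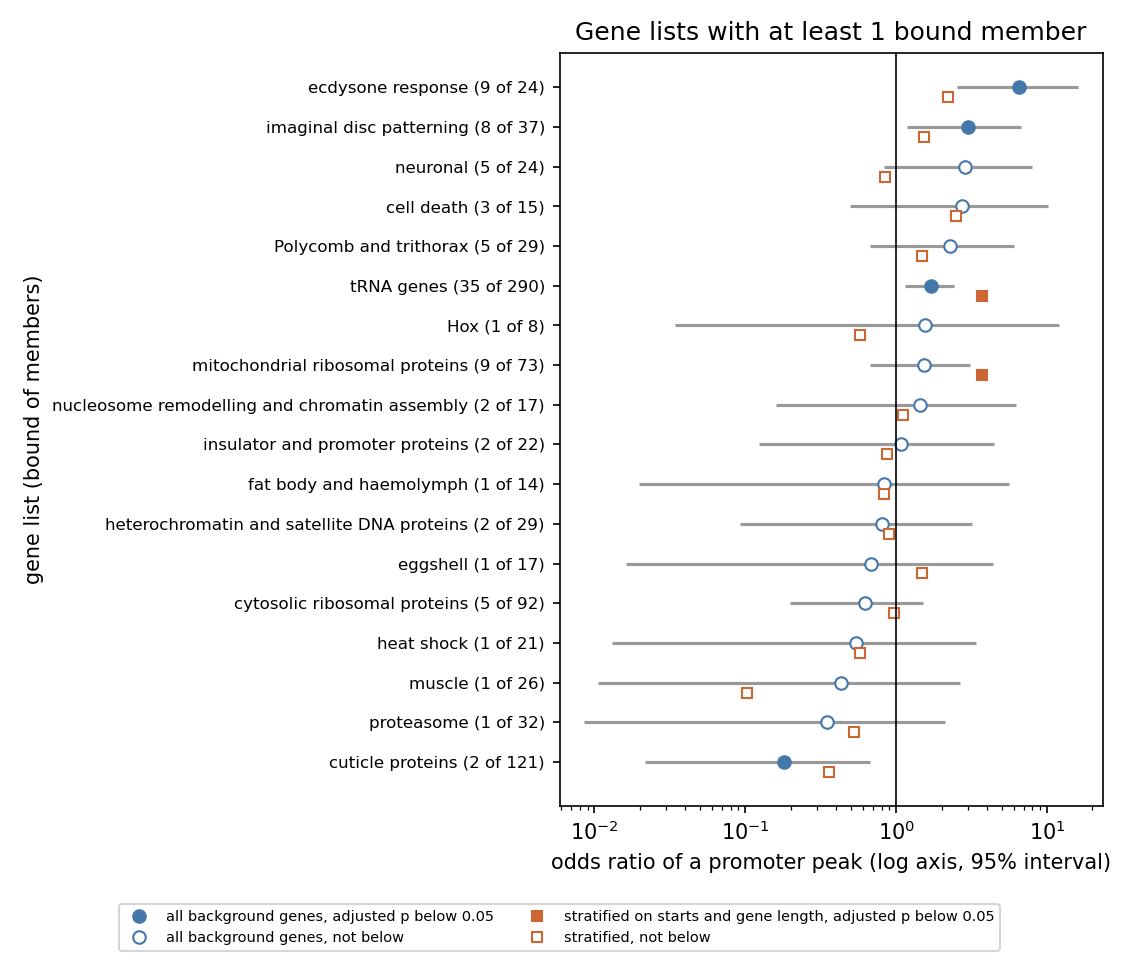
Odds ratio of a promoter peak for each gene list with at least 1 bound member, on a log axis with 95% intervals (circles), and the odds ratio within strata of start number and gene length (squares). The ecdysone response list lies highest among the circles, at 6.54, and at 2.20 within the strata.

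The D1 gene, from which the fusion was made, lies on 3R at 9238083 to 9240654. Within it and 5 kb on either side lay 3 IDR peaks. The highest, at 9239973 to 9240392, had a signal of 845 and its summit 84 bp downstream of a start, with signals of 391 in replicate 1 and 485 in replicate 2. The others had signals of 211 and 147. How much of this sequence the transgene holds is not given in the sources used here, and its copy number was not measured.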

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

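The 170 results were computed under 738 alternatives in all: 561 kept direction and side of the threshold, 123 kept direction and lost the threshold, 6 gained it, 44 changed direction and 4 counts moved by over 1.5 times. The densities on 2R, 3L and X, the shares in promoters, coding exons, intergenic sequence and proximal segments, AT content, A/T runs, mean promoter signal and the overlap of the replicates' highest peaks kept direction and threshold in every alternative run. The density on Y did so too, but no list held a peak there, so no alternative could change its direction. The excess of AT content ranged from 3.43 points in 500 bp windows to 9.01 in 100 bp windows, and the promoter share from 24.0% at 250 bp to 49.2% at 1000 bp. Of 106 named or listed genes with an IDR summit within 500 bp of the start used, 92 had a summit that near without replicate 1, 79 without replicate 2, and 55 among the 1694 highest peaks. That last setting has fewer peaks by construction. No paired analysis was possible because there is 1 group. Read depth is unknown, so what it limits could not be measured.

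Among the 1694 highest peaks the density ratio was 1.08 on 2L, 0.934 on 3R and 1.40 on chromosome 4, none past the threshold, the intron share was 39.4%, and the ratios of AAGAGAAGAG (0.691) and CGATA (0.974) fell below 1. Odds ratios changed side for heat shock (1.05), Hox (0), heterochromatin (1.56), insulator (1.00), fat body (1.62), tRNA (0.765) and eggshell (1.31) genes, and 2 lists passed instead of 6. Leaving out each replicate in turn gave density ratios of 1.06 to 1.11 on 2L and 0.894 to 0.967 on 3R. It gave word ratios of 0.970 to 1.08 for GAGAG, 0.956 to 0.964 for CGATA and 0.743 to 2.97 for AATAACATAG. Odds ratios were 1.11 to 1.80 for heat shock, 0.659 to 0.674 for nucleosome remodelling, 0 to 1.54 for Hox and 0.958 to 2.16 for neuronal genes.

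In 100 bp windows AAGAGAAGAG had a ratio of 0 and CGATA 0.967. In 500 bp windows AAGAGAAGAG had 0.974, GAGAG 1.19 and CGATA 0.948. With AT content matched, AATAACATAG had 0.912, AAGAGAAGAG 0.958, ATATATAT 0.813, GAGAG 1.32 and CGATA 0.983, and 6 words passed instead of 10. With starts within 1000 bp the odds ratio of muscle genes was 1.10, and over gene bodies those of fat body (1.19) and haemocyte (1.30) genes rose above 1. Among genes with no other start within 1 kb, which are fewer, odds ratios were 1.85 for cytosolic and 0 for mitochondrial ribosomal proteins, 1.23 for proteasome, 1.58 for heat shock, 1.39 for heterochromatin, 1.23 for fat body and 0.767 for tRNA genes, and 2 lists passed. Within strata of start number and gene length, chosen after seeing the data, they were 0.575 for Hox, 0.868 for insulator, 0.845 for neuronal and 1.48 for eggshell genes, and 3 lists passed. Beyond the fewer peaks or genes of some settings, the cause was not tested.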

Other observations

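The 6-base words, the counts of peaks inside each Hox gene, the peaks missing from a replicate, the composition at equal distance from a start and the test between the ecdysone and imaginal disc lists were chosen after the results were seen. Among the Hox genes, Antp held 5 IDR peaks in its gene body, Abd-B 3, and Ubx and pb 1 each, while Dfd had a peak at its start. When a summit in the gene body counted, 1711 of 13968 coding genes (12.2%) were bound. The share was higher in 4 lists by Fisher's exact test: 16 of 24 ecdysone response genes (odds ratio 14.4, adjusted p of 8.08e-09), 15 of 37 imaginal disc patterning genes (4.92, 7.91e-05), 5 of 8 Hox genes (12, 0.00446) and 9 of 29 Polycomb and trithorax genes (3.23, 0.0211). Antp spans 102976 bp, and gene length was not matched in these body tests. Promoter peaks of the Polycomb and trithorax list lay at ph-p (signal 636), E(z) (321), Pc (238) and pho (221), all of which encode Polycomb group proteins, and at Trl.

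Of all 2080 words of 6 bases, 236 were more frequent and 304 less frequent at IDR summits than in random windows also matched on AT content, at an adjusted p under 0.05. CAGTGC lay furthest above the random sets in units of their SD, in 14.3% of windows against 6.44%, a ratio of 2.23, followed by ACAGTG (2.15) and ACACTG (1.82). GAGAGA had a ratio of 1.75 and CAGGAC one of 0.453. Annotated transposable elements held 16 IDR summits (0.472%) against 6.14% of random positions. Those positions included repeated sequence, where reads may not be placeable, and the comparison was not limited to unique sequence. It therefore leaves open whether D1-eGFP avoids these elements. The 26612 pooled peaks below the IDR set were at 604 per Mb on chromosome 4 against 199 over the genome, with 19.1% in promoters and 2.19% in coding exons.

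Of the 37 IDR peaks missing from a replicate's list, 18 were missing from replicate 1 and 19 from replicate 2, and 5 were among the 100 highest. The pooled signal less that of the other replicate ranged from 26.2 to 557 over these 37 peaks. It was 557 at CG14100, against 567 in replicate 1, and at the next highest such peak 324, against 348 in replicate 1. On 2R it was 26.2 at 11149995 to 11150414, against 131 in replicate 2, and 38.5 at 9861020 to 9861439, against 141 in replicate 2. Some remainders were thus small beside the other replicate's signal. The lowest listed signal was 20.2 in replicate 1, with a median of 31.4, and 24.9 in replicate 2. Every remainder was above the lowest signal of the list that lacked the peak. A missing entry therefore does not by itself show that signal was absent. Over the 3114 IDR peaks with a summit of each replicate within 100 bp, the pooled signal was 1.00 times the sum of the replicates' signals at the median (quartiles 0.984 and 1.02). Whether the lists share a scale is not given in the sources used here, and why these entries are missing is open.

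Peaks lay in A/T-rich sequence, and 3 technical explanations were tested. At equal AT content the density in promoters was 3.94 times that elsewhere (3.67 to 4.22), which argues against AT content alone setting where peaks lie. Promoter peaks had 6.83 points more AT than the same distances from starts of unbound genes (66.5% against at most 60.5% in 1000 sets), which argues against the usual composition of such DNA. Pooled peaks below the IDR set were still 2.37 points above matched positions, which argues against a property of the strongest peaks alone. A part played by base composition bias, chromatin opening and the antibody's background stay open, since neither an open-chromatin map nor untagged flies were analysed here, and with 1 group no biological explanation was tested.

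Few peaks lay in the centromere-proximal segments, although D1 is known from satellite DNA, and the deficit was smaller in the lower pooled peaks (a ratio of 0.202). Over unique sequence outside transposable elements the segments held 0.129 of the expected peaks (0.0828 to 0.192), which argues against unplaceable reads as the whole cause, and matched on feature class they held 0.0618 (0.0396 to 0.0920), which argues against few gene features. Unique 31-base words made up 41.0% of the segments against 94.7% outside, so part of the deficit may come from repeats. Filters by the authors, chromatin state and the control's coverage stay open, and no biological explanation was tested.

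Ecdysone response genes often carried a promoter peak. Random lists matched on start number held 9 or more bound genes in 1.99% of 10000 draws, which argues, though only weakly, against start number alone. Lists matched on start number and gene length did so in 5.87%, so long genes with many starts are a candidate explanation. The ecdysone and imaginal disc lists could not be separated (Fisher's exact test, p = 0.244), since so few genes leave open whether developmental regulators in general share this. No biological explanation was tested.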
